A study of Arabidopsis thaliana with 6 samples.

How the data were processed

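RNA of 6 samples was hybridised to Affymetrix ATH1 arrays, 3 of the wild type and 3 of the apk1 apk2 double mutant. Per the labels' protocols, the RNA of a sample came from 10 pooled rosettes of plants grown for 35 days at 22 °C and 60% humidity with 10 h of light and 14 h of dark, and RNA was labelled with a kit that copies transcripts from their 3′ ends. Genotype and replicate number were taken from the sample labels.

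The values used were the deposited intensities, 1 linear signal per probe set and array. The submitters' processing notes name MAS5 and GCOS, without versions. Each array had been scaled by the authors: in the deposited table the mean without the top and bottom 2% of probe sets is 100.01 on every array. MAS5 detection calls were not used here. Values of dim probe sets are therefore noisy on the log2 scale, and the smallest signals were under 0.1. Scaling each array to 1 mean assumes that total signal is equal in both genotypes, so an overall change of transcript amount would not be seen. For arrays, their number, 3 per genotype, limits the precision.

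The table held 22810 probe sets. Of these, 64 control probe sets were left out of the comparison, and a probe set was tested if its signal reached its array's 40th percentile on at least 3 of 6 arrays, which left 13848. The 40th percentile lay between 16.9 and 19.4 and also served as the limit under which a signal was treated as a bound: where all 3 arrays of a genotype lay under it, the fold is given as "at least", with the mean log2 signal of the brighter genotype set against the mean of, per array, the higher of the limit and the measured signal. It is not a measured background. Values were taken to log2 without an offset. No further normalization was applied, because the arrays' median log2 values differed by 0.08, under the 0.2 set before. No pair of arrays shared identical values.

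Each probe set was fitted with limma 3.58.1 (R 4.3.3), lmFit and eBayes with a trend of the variance on the signal, with genotype alone as the factor. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Every adjusted p of a gene comes from this fit, folds are 2 to the power of the fitted log2 change, and 95% intervals come from the same fit without adjustment. The exact permutation test of 3 against 3 values cannot give a two-sided p under 0.1 and so was not used for single genes. On simulated data for the comparison of double mutant and wild type over 13848 probe sets, with 200 changed, the fit recovered 34% of 50 changed by 1.5-fold, 64% of 50 at 2-fold, 96% of 50 at 3-fold and 100% of 50 at 4-fold, with 3 false calls among 150. In that setting the comparison would miss many changes under 2-fold. The data had 1571 calls, far more than the 200 simulated changes. The adjusted threshold loosens with more changes, so recovery in the data may have been higher than these shares.

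Genes were named through a table that pairs probe sets with the platform annotation, and symbols were updated through the gene identifier with a gene table of the assembly TAIR10.1. Apart from the controls, 13513 probe sets named 1 gene, 503 several and 8730 none, and 13436 of the first matched the gene table. A probe set that named several genes or none was given no gene name; it is unnamed here, not without a gene. Genes with no symbol in the gene table are given by locus. No coordinates are given, because no genome build is named for the values.

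There were 23 gene lists, fixed by locus before the data were examined: APS kinases, sulfotransferases and PAPS use, aliphatic and indolic glucosinolate biosynthesis, glucosinolate regulators, glucosinolate breakdown and transport, sulfate uptake and assimilation, sulfur deficiency, glutathione and methionine, tryptophan, auxin, jasmonate, salicylate, sulfated peptides, oxidative stress, flavonoids, phosphate starvation, photosynthesis, senescence, cell division, root, floral and clock markers. Of their 311 different genes, 41 were tested, since the probe table named few of the others, and a list's result speaks only for its tested members. A gene with several probe sets was represented by the one with the highest mean log2 signal. Of 68 genes with over 1 tested probe set, 0 had calls in both directions and 5 were called on some probe sets and not on others. The 8 lists with at least 3 tested members were tested with limma's camera with a preset correlation of 0.01 and with an estimated one, with adjustment over the 8 lists, and with fry, which asks whether the members move, on balance, one way. Fry's adjusted p was 1.75e-04 for aliphatic glucosinolate biosynthesis, 0.00819 for both flavonoids and sulfate assimilation, 0.0286 for glutathione and methionine, and 0.238 to 0.456 for the other 4.

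Genes were chosen for the text by a rule set before the data were examined: the 4 APS kinases; among called probe sets that name 1 gene and whose groups do not overlap, the 12 largest increases and 12 largest decreases in log2; and for each list up to 5 called members with the largest change or, with no call, the member with the smallest adjusted p. Other genes are named as examples, chosen after their values were seen. The ranking by fitted log2 change favours dim probe sets.

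Alternatives tried were quantile normalization, median centring, no filter, a 60th percentile filter, an offset of 3.60 (the 20th percentile of all values) before log2, eBayes without a trend or robust, array weights, the replicate number as a block, a 2-fold threshold, an adjusted p under 0.01, and leaving out each array in turn; for lists also the mean of a gene's probe sets.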

Results

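The series measured transcript levels in rosettes of Arabidopsis thaliana on 6 Affymetrix ATH1 arrays, 1-colour oligonucleotide arrays on which each gene is read by 1 or more probe sets. Of these, 3 arrays came from the wild type Col-0 and 3 from a double mutant lacking the APS kinases APK1 and APK2. APS kinase phosphorylates adenosine phosphosulfate to PAPS, the sulfate donor of sulfotransferases, which also carry out the last step of glucosinolate core synthesis. Each sample was RNA from a separate pool of 10 whole rosettes, cut 35 days into growth in a 10 h day and 4 h after the lights came on. The arrays had near-equal median signals, between 32.5 and 34.5. Across tested probe sets, pairs of wild-type arrays correlated at 0.981 to 0.986 on the log2 scale, pairs of mutant arrays at 0.974 to 0.983, and pairs of different genotypes at 0.950 to 0.969. The comparison of the genotypes asked which transcripts change when these APS kinases are lost.

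The double mutant had higher transcript levels of the tested glucosinolate biosynthesis genes and of the plant defensin PDF1.2, while genes of sulfur metabolism moved in both directions. Few glucosinolate biosynthesis genes were tested, 4 of 28 on the aliphatic list and 1 of 16 on the indolic list. BCAT4, which starts methionine chain elongation in aliphatic glucosinolate synthesis, was 4.13-fold higher (95% interval 3.69 to 4.63, n = 3 per genotype). PDF1.2, a defensin commonly used as a marker of jasmonate and ethylene responses, was 7.62-fold higher (95% interval 5.04 to 11.5). XTH19, a xyloglucan endotransglucosylase/hydrolase, was 3.31-fold lower (95% interval 2.33 to 4.71), and the ATP sulfurylase APS4 1.52-fold lower (95% interval 1.26 to 1.84). In all, 1571 of 13848 tested probe sets passed an adjusted p of 0.05 with limma, 802 of them higher and 769 lower in the mutant. At least 2-fold changes were more often increases, with 250 probe sets higher and 81 lower. Over all 13848 tested probe sets the 2 genotypes did not overlap in 3969, or 28.7%, where chance alone gives 10%. The count of called probe sets, 1571 with all arrays, was 1030 without wild-type replicate 3 and 1029 without mutant replicate 3, and 880 with a variance prior that ignores the signal level. A gene name was at hand for part of the array: of the 1571 probe sets, 742 named 1 gene, 28 named several and 801 named none.

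**Figure D1:**
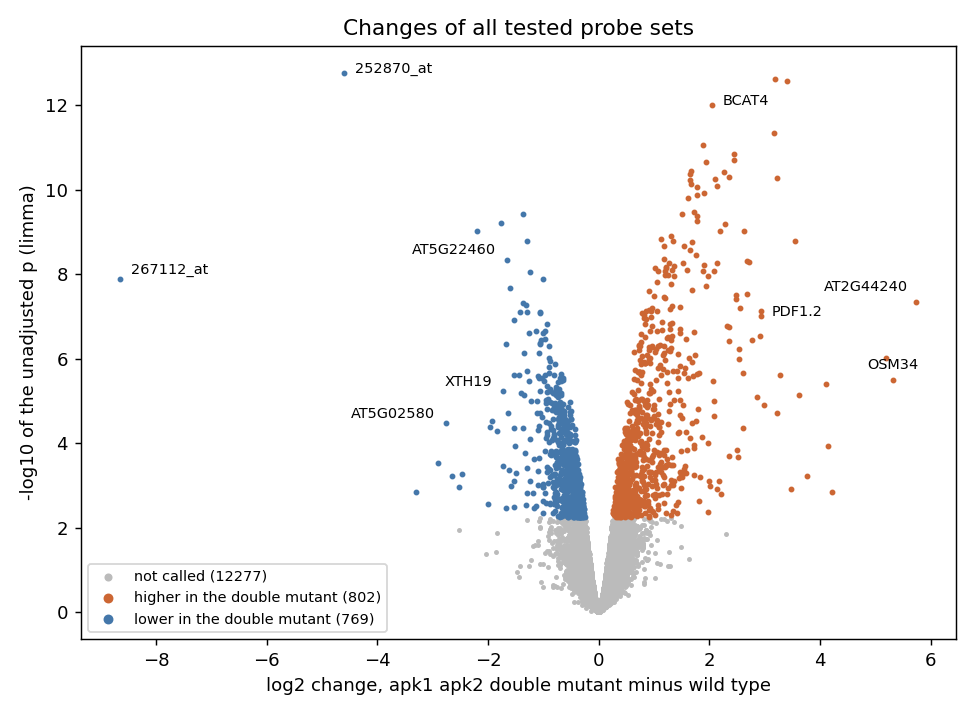
Each point is 1 of the 13848 tested probe sets, with the log2 change (double mutant minus wild type, 3 arrays each) on the horizontal axis and −log10 of the unadjusted limma p on the vertical axis. The 802 probe sets called higher lie to the right and the 769 called lower to the left. The point farthest left, 267112_at, has mutant signals under the 40th percentile on all 3 arrays, so its place is not a measured fold.

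None of the 4 APS kinases, the disrupted APK1 and APK2 included, had a probe set named in the probe table used here. Their levels in each array are therefore not reported, and the labels were not checked against the targeted transcripts.

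All 4 tested genes of the list for aliphatic glucosinolate biosynthesis rose. BCAT4 went from a mean signal of 965 ± 56.1 (SD, n = 3) in the wild type to 3981 ± 107 in the mutant, with an adjusted p of 3.43e-09. GSTU20, a glutathione transferase, went from 1093 ± 121 to 3329 ± 122, a 3.06-fold rise. The glucosyltransferase gene AT2G31790 rose 2.26-fold and the dioxygenase gene AT2G25450, which acts in side chain modification, 2.03-fold. Over the list the median log2 change was 1.39 (camera with a preset correlation, adjusted p = 4.19e-13 over 8 lists). With an estimated correlation the adjusted p = 0.10, so the list's shift was no longer past the threshold. Adjusted over the list alone, the count was also 4. Of the 28 genes on the list, the other 24 were not tested here, among them AOP3, whose signal lay under the 40th percentile on all 6 arrays. From the list for indolic glucosinolates, UGT74B1 was the 1 gene tested, a glucosyltransferase that serves both classes. It rose 2.45-fold (95% interval 2.05 to 2.92), from 339 ± 63.9 to 821 ± 54.4. AT2G04400, the indole-3-glycerol phosphate synthase gene and the 1 tested gene of tryptophan biosynthesis, rose 2.37-fold (95% interval 1.93 to 2.92, adjusted p = 5.58e-05). Each was also past the threshold adjusted over the list alone.

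The tested regulators of the pathway did not pass the test, but most of the 14 on the list were not tested. The MYB factors on the list, MYB28 and MYB34 among them, were all untested, so nothing can be said about them. Of 3 tested genes, 0 were called, over all genes and adjusted over the list alone, and the list's median log2 change was −0.12 (camera, adjusted p = 0.553). The signal of MYC4 was 105 ± 20.7 in the wild type and 96.8 ± 18.6 in the mutant (SD, n = 3), and that of MYC3 94.3 ± 4.66 and 97.1 ± 12.5. AT1G04770, which is also the 1 tested marker of sulfur deficiency, had 158 ± 13.3 and 130 ± 25.9 (adjusted p = 0.211). Without mutant replicate 1 its adjusted p was 0.0317, with a log2 change of −0.45, and over its alternatives the adjusted p ranged from 0.0317 to 0.489. Of the 2 tested genes for glucosinolate breakdown and transport, the transporter GTR2 rose 1.33-fold (95% interval 1.14 to 1.55, adjusted p = 0.0193), and this was the 1 call adjusted over the list alone. The GTR2 call ended without wild-type replicate 2 (adjusted p = 0.0703), wild-type replicate 3 (0.0904) or mutant replicate 3 (0.0841). GTR1 had 332 ± 26.6 in the wild type and 383 ± 46.8 in the mutant (adjusted p = 0.262).

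Both tested genes on the list for sulfotransferases and PAPS use rose, also adjusted over the list alone. TAAC, a plastid carrier that also transports PAPS, rose 2.51-fold (95% interval 2.1 to 3.0), from 82.6 ± 5.26 to 208 ± 29.0 (SD, n = 3). HL, a phosphatase that removes the PAP left by sulfotransferases, rose 1.63-fold. Of 3 tested genes of sulfate uptake and assimilation, the ATP sulfurylase APS3 rose 1.99-fold, the sulfite reductase SIR rose 1.39-fold and the ATP sulfurylase APS4 fell 1.52-fold, from 159 ± 11.7 to 105 ± 16.1. All 3 were also called adjusted over the list alone. As a list they had a median log2 change of 0.47 and did not pass camera (adjusted p = 0.0800, and adjusted p = 0.428 with an estimated correlation). Among 5 tested genes of glutathione and methionine metabolism, cystathionine beta-lyase CBL rose 1.95-fold (95% interval 1.71 to 2.22), glutathione reductase GR1 rose 1.39-fold and methionine gamma-lyase MGL fell 1.82-fold (95% interval 1.41 to 2.34). The remaining 2 were not called, and 3 members were called adjusted over the list alone. The list had a median log2 change of 0.11 (camera, adjusted p = 0.233; median 0.061 to 0.17 over the alternatives).

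**Figure D2:**
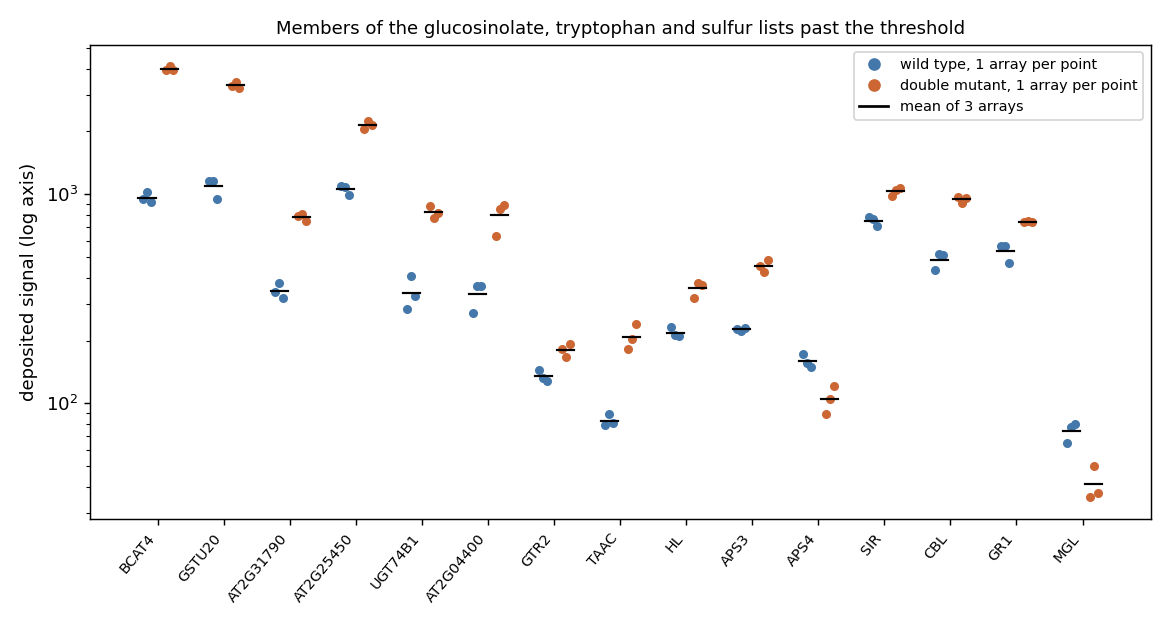
Deposited signal (log axis) of 15 genes from the glucosinolate, tryptophan and sulfur lists, with 1 point per array and a black line at the mean of 3 arrays. The double mutant points lie above the wild-type points for 13 genes, with BCAT4 at a mean of 3981 against 965, and below them for APS4 and MGL.

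The largest increases that could be given a gene name included genes with low signal in the wild type. For 8 of these 12 genes all 3 wild-type arrays lay under their array's 40th percentile of signal, between 16.9 and 19.4, so their rise is given as a lower bound against that limit. AT2G44240 was at least 6.15-fold higher, with 2.59 ± 2.32 in the wild type and 106 ± 6.34 in the mutant (SD, n = 3, adjusted p = 7.96e-06). OSM34, an osmotin-like protein, was at least 5.28-fold higher, AT2G19970 at least 4.32-fold and AT3G13610, the F6'H1 hydroxylase of scopoletin synthesis, at least 3.89-fold. AT2G22930 was at least 3.33-fold higher, the berberine bridge enzyme-like gene AT1G26390 at least 2.41-fold, AT5G23830 at least 1.95-fold and AT2G30840 at least 1.30-fold. AT4G24130, above the limit in 2 of 3 wild-type arrays, rose from 19.0 ± 6.86 to 210 ± 21.

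Well above this limit, the defensin PDF1.2b rose 9.37-fold (95% interval 7.33 to 12.0). Its probe set is of a kind that can also bind related transcripts. PDF1.2, the 1 tested member of the jasmonate list and called adjusted over the list alone, went from 320 ± 72.8 to 2606 ± 1164 (SD, n = 3, adjusted p = 1.34e-05). The chitinase family gene AT2G43590 rose 7.97-fold (95% interval 4.13 to 15.4), from 36.6 ± 2.16 to 368 ± 255. Mutant replicate 1 had the lowest signal of the mutant arrays for both, 1309 against 2948 and 3560 for PDF1.2 and 105 against 385 and 613 for AT2G43590. The log2 change of AT2G43590, 2.99 with all arrays, was 3.73 without mutant replicate 1 and 2.46 without mutant replicate 3. A robust variance prior ended its call (adjusted p = 0.0580).

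The calls of 3 dim genes ended when single mutant arrays were left out, although in those settings their log2 changes moved little. That of AT1G26390, 4.22 with all arrays, was 4.10 without mutant replicate 2 and 4.19 without mutant replicate 3. For AT5G23830 it was 3.49 with all arrays, and 3.39 and 3.36 without these. For AT2G30840 it was 3.76 with all arrays, 3.73 without mutant replicate 1 and 3.78 without mutant replicate 3. Without mutant replicate 2 the adjusted p was 0.0691 for AT1G26390 and 0.0619 for AT5G23830, without mutant replicate 3 it was 0.0775, 0.0841 and 0.0792 for AT1G26390, AT5G23830 and AT2G30840, and without mutant replicate 1 it was 0.0543 for AT2G30840.

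Decreases among the named genes were smaller. AT5G22460 fell 3.15-fold (95% interval 2.63 to 3.78), from 206 ± 26.1 to 65.0 ± 4.88 (SD, n = 3, adjusted p = 1.44e-06), and AT4G22490 fell 2.67-fold (95% interval 2.20 to 3.26). AT5G28630 fell 2.64-fold and AT3G60290 2.56-fold. XTH19 went from 48.7 ± 2.19 to 15.0 ± 3.66, with 1 of 3 mutant arrays above its 40th percentile, as for AT3G46490, which fell 3.59-fold. AT5G47330, above it in 2 of 3 mutant arrays, fell 2.86-fold. The mutant arrays all lay under the limit for 5 genes. XTH18 was at least 1.73-fold lower, AT5G02580 at least 1.71-fold, AT1G78450 at least 1.61-fold, AT4G16563 at least 1.5-fold and AT3G07530 at least 1.12-fold. Without wild-type replicate 1 the adjusted p was 0.0554 for XTH18, 0.0620 for AT4G16563 and 0.106 for AT1G78450. Without wild-type replicate 2 it was 0.0534 for AT4G16563, 0.0836 for AT1G78450 and 0.0539 for AT3G07530, and without wild-type replicate 3 it was 0.10 for AT1G78450 and 0.0875 for AT3G07530. Quantile normalization also ended the call of AT1G78450 (adjusted p = 0.0554, and 0.0116 to 0.106 over its alternatives).

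**Figure D3:**
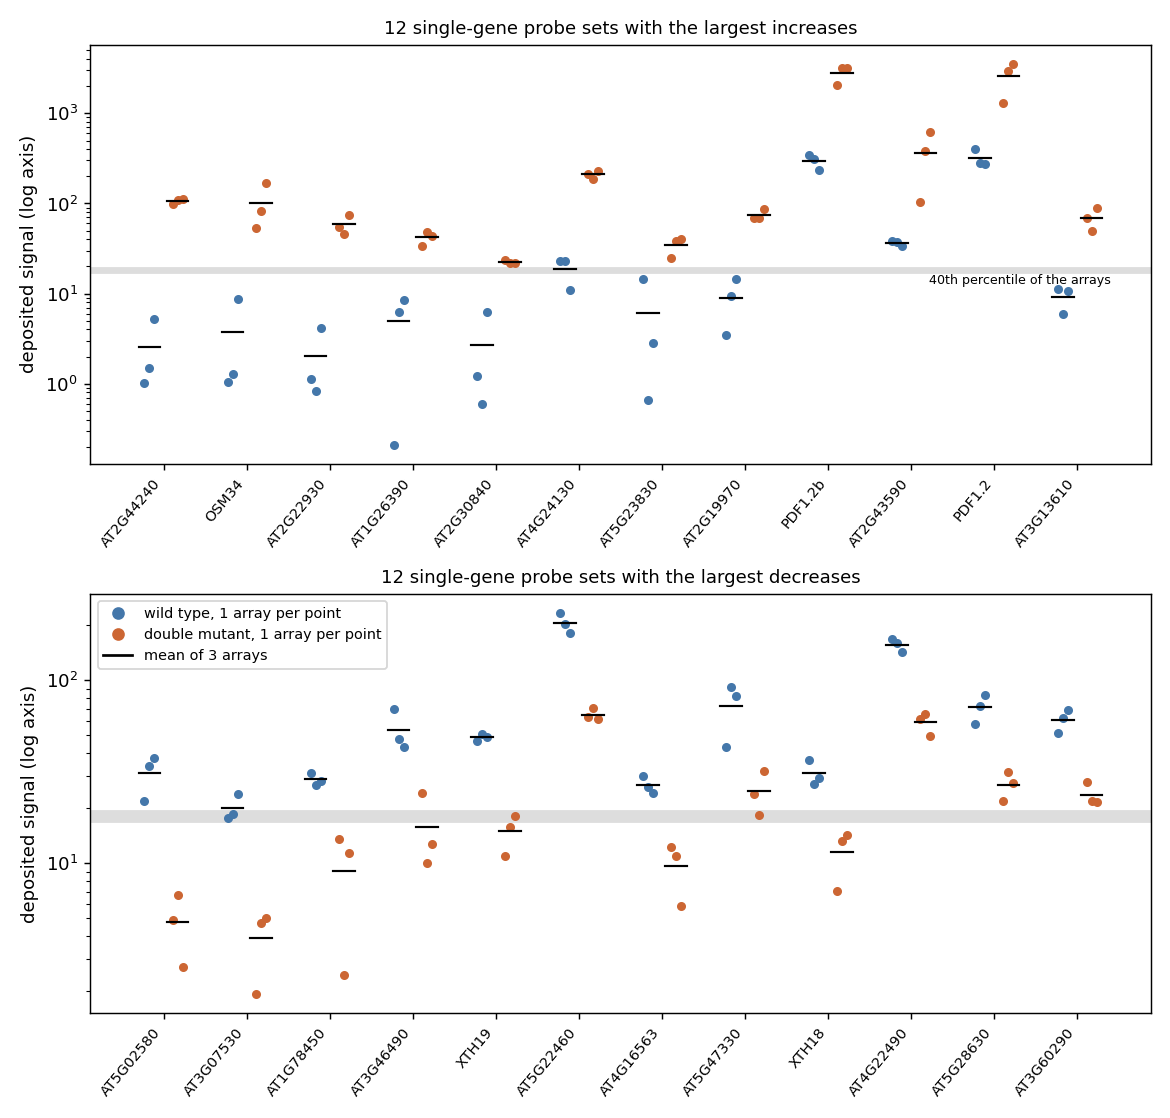
Deposited signal (log axis) of the 12 named genes with the largest increases (top) and the 12 with the largest decreases (bottom), with 1 point per array, a black line at the mean of 3 arrays and a grey band at the arrays' 40th percentiles, 16.9 to 19.4. All wild-type points lie under the band for 8 of the top genes, and all mutant points lie under it for 5 of the bottom genes.

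Larger falls were seen in probe sets without a gene name, chosen here after their values were seen. The signal of 267112_at was 555 ± 49.7 in the wild type and 2.49 ± 2.89 in the mutant (SD, n = 3), at least 31.0-fold lower (adjusted p = 2.66e-06). That of 252870_at fell 24.4-fold (95% interval 19.5 to 30.4), from 457 ± 24.1 to 19.0 ± 3.82. Of the unnamed probe sets above the limit in both genotypes, 258322_at rose 10.5-fold (95% interval 8.90 to 12.5) and 249867_at 9.10-fold (95% interval 7.77 to 10.7).

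Flavonoid and anthocyanin genes rose as a list, with a median log2 change of 0.89 over 4 tested genes (camera, adjusted p = 0.00230). With an estimated correlation the adjusted p = 0.10. Without the filter on low signal, which adds AT5MAT, the median was 0.50 (adjusted p = 8.24e-04). Of the 4, 2 were called, and 3 adjusted over the list alone. The reductase DFR rose 2.41-fold (95% interval 1.86 to 3.13), from 36.6 ± 7.54 to 87.4 ± 10.9 (SD, n = 3). The anthocyanin glucosyltransferase gene AT4G14090 rose 2.62-fold (adjusted p = 0.0318), with 1 of 3 wild-type arrays above the 40th percentile. Its adjusted p was 0.108 without wild-type replicate 2, 0.0958 without wild-type replicate 3, 0.0719 without mutant replicate 2 and 0.176 without mutant replicate 3.

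Auxin genes went both ways. IAA29, a repressor of auxin responses, fell 1.46-fold (95% interval 1.22 to 1.74, adjusted p = 0.0102), and GH3.3, which conjugates auxin to amino acids, rose 1.62-fold (adjusted p = 0.0430). The other 2 tested genes were not called, 3 were adjusted over the list alone, and the list's median log2 change was −0.11 (camera, adjusted p = 0.553; −0.33 to 0.11 over the alternatives), while its mean was −0.02. The IAA29 call ended without wild-type replicate 3 (adjusted p = 0.0541, and 0.00303 to 0.0597 over its alternatives). That of GH3.3 ended without wild-type replicate 1 (0.171) or 2 (0.111) and without mutant replicate 2 (0.0972) or 3 (0.179).

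Of 3 tested photosynthesis genes, the Calvin cycle enzyme SBPASE fell 1.26-fold (95% interval 1.11 to 1.43, adjusted p = 0.0245), and it was the 1 call adjusted over the list alone. The list's median log2 change was −0.11 (camera, adjusted p = 0.344), and it lay between −0.18 and −0.019 over the alternatives. The SBPASE call ended when any array other than mutant replicate 1 was left out, with adjusted p-values of 0.0785, 0.0583 and 0.0636 without wild-type replicates 1, 2 and 3 and of 0.0660 and 0.0919 without mutant replicates 2 and 3. Senescence genes had 0 calls among 3 tested, also adjusted over the list alone, with a median log2 change of 0.04 (camera, adjusted p = 0.467). WRKY53 had 73.8 ± 26.5 in the wild type and 106 ± 19.7 in the mutant (SD, n = 3, adjusted p = 0.119), and it passed with the replicate number as a block (adjusted p = 0.0195) and without wild-type replicate 3 (adjusted p = 0.0109), with adjusted p-values up to 0.353 under other settings.

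No tested member of the remaining lists was called, over all genes or adjusted over the list alone. The smallest adjusted p among 2 oxidative stress genes was that of AT2G21640, with 29.7 ± 7.47 in the wild type and 32.9 ± 2.81 in the mutant (SD, n = 3, adjusted p = 0.696). The 1 tested receptor of sulfated peptides, PSY1R, had 26.7 ± 6.76 and 29.6 ± 8.38 (adjusted p = 0.799). The cell division gene AUR1 had 36.8 ± 0.555 and 36.5 ± 14.3 (adjusted p = 0.878), and the clock gene GI had 87.9 ± 14.4 and 99.5 ± 7.25 (adjusted p = 0.455). The lists for salicylate and pathogen response, sulfolipid and phosphate starvation, flowering and root markers had no tested member. The 2 root markers with a named probe set, EXPA7 and EXPA18, lay under the 40th percentile on all 6 arrays.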

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

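Among 35 control probe sets with enough signal, which served no comparison above, 1 passed an adjusted p of 0.05 with limma as higher in the double mutant and 0 as lower. This was a probe set for the 5′ part of GAPDH, a glycolysis gene used as a quality control, with 1997 ± 121 in the wild type and 2385 ± 67.2 in the mutant (SD, n = 3), a log2 change of 0.26 (adjusted p = 0.0458). The matching 3′ probe set had 2064 ± 67.5 and 2383 ± 136 (adjusted p = 0.111). The other 3 GAPDH probe sets were not called, with log2 changes of 0.23 (middle part, adjusted p = 0.0619), 0.14 (5′, adjusted p = 0.312) and 0.03 (3′, adjusted p = 0.861).

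The split of the 6 arrays by genotype called 1571 probe sets, and the highest count among the other splits into 3 and 3 was 0. As many calls came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.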

How the results depend on the processing

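All alternatives here were planned. The 1571 calls (802 higher, 769 lower) became 880 (507, 373) without a variance trend, 331 (250, 81) with a 2-fold threshold and 811 (466, 345) with an adjusted p under 0.01, and 1029 to 1585 (526 to 791 and 444 to 794) when 1 array was left out. Stricter limits lower counts by construction; the cause of the other drops was not tested. Other settings stayed within 1.5 times of these counts. The labels do not say whether replicate numbers pair the samples, and the data leave it open. Deviations of same-numbered arrays correlated weakly, at 0.08, 0.08 and 0.11, and those of differently numbered arrays at −0.083 to −0.003. Each array thus correlated best with its own number, a weak hint from the data only. Deviations were taken from the mean of each genotype, so positive values for same-numbered arrays force negative ones elsewhere. The negative values are therefore no separate evidence. With the replicate number as a block the counts were 1789 calls, 883 higher and 906 lower, with 1535 of the 1571 kept in their direction; no list's call changed, and WRKY53 passed (adjusted p = 0.0195).

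With an estimated correlation the shifts of aliphatic glucosinolate biosynthesis (median log2 change 1.39) and flavonoids (0.89) lost their call, both with an adjusted p of 0.10. Without a filter the shift of sulfate assimilation passed (median 0.47, adjusted p = 0.0369, and 0.0369 to 0.428 over its alternatives). Medians that were not called changed sign: glucosinolate regulators ranged from −0.26 to 0.020 when 1 array was left out (4.2e-04 without wild-type replicate 1 and 0.020 without mutant replicate 2), auxin genes were at 0.11 without a filter, −0.33 with the 60th percentile filter and −0.18 to 7.7e-04 when 1 array was left out, and senescence genes −0.12 to 0.29. The cause was not tested. For 54 named genes and probe sets under these settings, 824 of 899 values kept direction and side of the threshold, 70 lost the call, 3 gained it, and 2 uncalled genes changed sign, PSY1R to −0.080 without mutant replicate 2 and AUR1 to 0.16 without mutant replicate 1, within −0.080 to 0.34 and −0.38 to 0.16 when 1 array was left out.

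The prior without a trend ended 9 single calls (AT1G26390, AT5G23830, AT1G78450, GTR2, GR1, GH3.3, IAA29, AT4G14090 and SBPASE), with adjusted p-values of 0.0504 to 0.161, and 4 ended without a filter (AT1G78450, GH3.3, AT4G14090 and SBPASE, 0.0615 to 0.0804). A robust prior ended those of AT2G43590 (0.0580), GH3.3 (0.0677) and AT1G26390 (0.0918), and array weights that of GH3.3 (0.0593). With the 60th percentile filter the flavonoid and senescence lists had too few tested members for a value. The targeted genes had no value under any setting. Low signal limits folds of genes near the 40th percentile.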

Other observations

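The groups in this part were chosen after the data were seen, as were the tests described here except those of scaling. The p-values of the lists in this part are therefore descriptive and give no independent support. Genes for protein folding in the endoplasmic reticulum were higher in the double mutant: 6 of 11 tested members of a list of 35 rose, 0 fell, and the median log2 change was 0.42 (camera, adjusted p = 2.67e-08 over 3 lists; adjusted p = 0.0618 with an estimated correlation). The calnexin gene AT5G07340 rose 1.81-fold, from 105 ± 22.8 to 187 ± 18.0 (SD, n = 3), the chaperone ATERDJ3B 1.77-fold, the transcription factor BZIP17 1.72-fold and the calreticulin CRT1b 1.58-fold. Counts of members called higher were 5 to 7 over the alternatives.

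Of 32 gene families with at least 5 tested members by symbol, 1 was enriched among called genes. Of 5 tested beta-tubulin (TUB) genes, 4 were lower in the double mutant (Fisher's exact test, one-sided, adjusted p = 0.0156 over 64 tests), among them TUB1 with a log2 change of −0.80 and TUB6 with −0.49. The count was 3 with quantile normalization, 4 with median centring, and 2 without wild-type replicate 3, without mutant replicate 3 or without a variance trend. XTH genes were lower in 3 of 5, a share that did not pass (adjusted p = 0.177).

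Transcripts of the plastid genome were lower in the double mutant: 30 of 66 tested genes were called lower and 0 higher, with a median log2 change of −0.31 (camera, adjusted p = 8.65e-17; adjusted p = 0.163 with an estimated correlation). The count was 9 without a variance trend, 12 and 17 without wild-type replicates 1 and 2, and 14 and 18 without mutant replicates 2 and 3. The fall differed with signal. The brightest genes were not called: atpB (wild-type mean 7043, log2 change −0.02), psbM (6916, 0.11) and atpE (6112, 0.02). Dimmer genes fell further, such as psbN (105, −0.90) and ndhH (75.9, −0.82), although petN (58.5, 0.28) did not. Scaling is argued against by quantile normalization, after which 33 were called lower. Median centring left 30, but it cannot decide the question, since the arrays' median log2 values differed by only 0.08. A difference in RNA quality stays open: the log2 ratio of 3′ to 5′ signals was higher in the mutant for 2 of 6 control pairs, both of actin, and lower for the 4 of GAPDH and ubiquitin, by −0.13 to 0.17, and only 1 pair, of ubiquitin, had a 95% interval that excluded 0. For less photosynthetic tissue as the whole cause, 20 nuclear photosynthesis genes were compared. Their median was −0.12 (95% bootstrap interval over genes −0.27 to 0.01) and lay above the plastid median by 0.19 (0.03 to 0.36). This cannot decide the question, since the plastid and nuclear sets were not matched for signal and genes are not independent replicates. The brightest plastid genes, atpB, psbM and atpE, fell no further than that nuclear median. The next brightest, petB (5088, −0.14) and psbA (5026, −0.15), fell slightly further. Less photosynthetic tissue stays open. A change of plastid transcript levels with genotype may also explain the pattern and stays open, as does a difference in how transcripts with few poly(A) tails are copied by the labelling kit, which was not tested.

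The fall of 267112_at and 252870_at stood apart. They were the 2 probe sets, of all tested, with a wild-type mean over 200 that were at or under a sixteenth of it in all 3 mutant arrays. A candidate explanation is that the 2 probe sets belong to the 2 disrupted genes. It stays open, because the probe table used here names neither, and another gene removed or silenced in this line would look alike.

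Some induced transcripts were weaker in mutant replicate 1. Of the 802 probe sets called higher, 12 lay at least 2-fold below the mean of the other mutant arrays there, PDF1.2, AT2G43590 and OSM34 among them, against 0 in each of the other mutant replicates. Scaling is argued against, as 12 remained after quantile normalization, and so is admixed wild-type RNA, since a median of 72.6% would be needed while 267112_at kept at most 3.07% and 252870_at at most 3.72% of their wild-type signal there, with signals under the 40th percentile counted at that limit. A smaller response of this pool in general may contribute: 56.9% of probe sets called higher had their lowest and 54.7% of those called lower their highest mutant signal in replicate 1, where 33.3% would be chance. The probe sets are read on the same pools and are not independent, so the distance from 33.3% is not a test. The median log2 response in replicate 1 was 83.7% and 82.4% of that of the other mutant arrays. The same measure was 99.4% and 107% for mutant replicate 2 and 119% and 112% for mutant replicate 3. Each array was set against the others, so a strong replicate 3 also lowers the figure of replicate 1. For the 12 the response in replicate 1 was 48.5%, but they were picked for being low, and no biological explanation within the pools was tested.

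Neighbouring genes were not called in the same direction more often than by chance: 8 of 2220 neighbouring pairs with both genes tested were, against a mean of 10.4 over 10000 random reassignments (permutation p = 0.82, one-sided). In another 8 pairs the directions were opposite. The neighbours MSRB5 and MSRB6, which encode methionine sulfoxide reductases, are an example, with a 3.16-fold rise (95% interval 2.78 to 3.59) and a 1.28-fold fall (95% interval 1.13 to 1.44).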
